A study of Mus musculus with 9 samples.

How the data were processed

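RNA from sorted mouse bone marrow cells was measured on 9 Affymetrix arrays, 3 for each of 3 groups (control, Runx1KO and RUNX1(41-214)). Per the labels, the RNA was isolated on Qiagen microcolumns and labelled with biotin by the Affymetrix two-cycle procedure, in which the material is amplified before hybridisation, so that ratios between genes within an array are not absolute amounts. The deposited values are a signal intensity per probe set on a linear scale, from 0.53 to 20215, with 22690 probe sets per array. The summarisation algorithm and any scaling are not given in the sources used here. The 9 arrays had similar but unequal trimmed means, so the deposited values were not quantile normalized.

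The 64 control probe sets were set aside, which left 22626. Signals were converted to log2(signal + 16), and an offset of this size pulls changes of dim genes toward 0, so that their folds are understated. The array medians on this scale spanned 0.211, above the limit of 0.2 set in advance, and the arrays were therefore quantile normalized. Gene names came from the probe set table supplied with the array: 20380 probe sets carried 1 gene symbol, 691 carried several and 1555 carried none. Of these, 20364 probe sets had a gene identifier found in the mouse RefSeq gene table (assembly GRCm38.p6), which changed 0 symbols and which served only for names and for which genes lie next to each other. Each gene was represented by its probe set with the highest mean over the 9 arrays, which gave 12393 genes. No filter on low signals was applied.

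A linear model with a mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend). The fit had 6 residual degrees of freedom per gene and 5.60 prior ones. The 3 contrasts tested two-sided were Runx1KO minus control, RUNX1(41-214) minus control and RUNX1(41-214) minus Runx1KO. P-values were adjusted by the Benjamini-Hochberg method over the 12393 genes of each contrast, with a threshold of 0.05 on the adjusted p. A moderated F test asked whether a gene differed among the 3 groups. Genes past the threshold in both contrasts against control were compared by direction, and since both contrasts share the 3 control arrays, their covariance was set beside 100 simulations of unchanged groups with shared controls. With 3 controls, separate control arrays could not be given to each contrast.

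The lists of genes were written before the data were examined: HSC-associated, quiescence and CDK inhibitors, cell cycle and proliferation, niche adhesion and homing, megakaryocyte and platelet, erythroid, granulocyte, monocyte, macrophage and dendritic cell, early lymphoid, B cell, T and NK cell, mast cell and basophil, stromal and endothelial, interferon-stimulated, immediate early and stress, NF-kB and inflammation, p53 targets, Runx family and partner factors, reported Runx1 targets, Hox and self-renewal factors, ribosome biogenesis and sex-linked. The 22 lists held 435 different genes, of which 389 were measured. Each list was compared with the other genes by camera with a preset inter-gene correlation of 0.01, adjusted over the 66 pairs of list and contrast. The same test was run with a correlation estimated per list, and fry was run as another set test.

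Genes are named by a rule written at the same time as the lists. It takes Runx1 in every contrast, and the 10 genes with the largest rise and the 10 with the largest fall per contrast among genes past the threshold whose arrays did not overlap between the groups and whose higher group mean exceeded the median of all genes, symbols of unnamed models excepted. It also takes up to 4 members per list past the threshold (or the 2 with the lowest p where none passed), up to 10 genes shared by both contrasts against control, and the 2 members of each other-cell-type list with the highest mean signal. A gene named outside the rule is said to have been chosen or named after its values were seen.

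Depth has no count for arrays, and the number of arrays limits the precision: the median standard error of a log2 fold change was 0.20. The procedure was tested on simulated data made from the residual spread of these arrays, with 200 of 12393 genes changed. For Runx1KO against control it recovered 19.4% of the genes changed by a fold of 1.5, 79.1% of those changed by a fold of 2 and 100% of those changed by a fold of 4, with 3 false calls among 135. The figures for RUNX1(41-214) against control were 23.9%, 67.2% and 100%, with 5 false calls among 132. For RUNX1(41-214) against Runx1KO they were 19.4%, 65.7% and 100%, with 6 false calls among 129. A simulated list shifted by 0.5 on the log2 scale had an adjusted p of 1.53e-06, and 0 of the 60 pairs of lists without its genes passed. Each gene was drawn independently in this simulation, so that it cannot show how often lists of correlated genes pass.

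Alternatives named in advance were the values without quantile normalization, offsets of 1 and 50, dim genes left out (below the 40th percentile), no variance trend, array weights, the mean of a gene's probe sets, all probe sets tested, a block for the replicate number, a minimum fold of 1.2 (treat), only the 6 arrays compared, an estimated correlation, fry, and each array left out in turn. An omission of the 2 arrays with the highest Gapdh 3′ over 5′ ratio was chosen after seeing the data. Arrays sharing a replicate number were checked for pairing: the correlations of their deviations from the group means ran from -0.17 to 0.42, with 3 of 9 above 0.1. Differently numbered arrays ran from -0.47 to 0.26. The highest values, 0.41 and 0.42, were those between control and Runx1KO replicates 2 and 3, so that a pairing of these groups was not excluded. The arrays were treated as unpaired. All 9 arrays were used, and no array was left out of the values reported.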

Results

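Gene expression was measured in KSL cells, the c-Kit-positive, Sca-1-positive, lineage-negative and IL7Ra-negative fraction of mouse bone marrow that holds haematopoietic stem cells and early multipotent progenitors. The study compared 3 groups on a C57BL/6 background, each with 3 biological replicates and 1 array per replicate. Control mice carried floxed Runx1 alleles without Mx-Cre, and Runx1KO mice carried the same alleles with Mx-Cre, which deletes Runx1, a transcription factor of blood development, after poly IC induction. Both groups were sampled 3 months after poly IC. RUNX1(41-214) cells expressed, from a retroviral vector, the part of RUNX1 from residue 41 to residue 214, which contains the DNA-binding Runt domain, and were sampled 4 months after transplantation. The labels of this last group name no poly IC treatment, and no array of transplanted cells with an empty vector was among the 9. Its differences from the other groups therefore also carry those of transplantation, transduction and poly IC.

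Median signals per array ran from 125 to 147. Over all genes, the correlation between arrays was 0.976 to 0.992 within groups and 0.968 to 0.986 between groups. The first principal component held 33.0% of the variance and placed the RUNX1(41-214) arrays at 26.3 to 31.2, the Runx1KO arrays at -9.22 to -5.25 and the control arrays at -25.1 to -16.8. The ratio of 3′ to 5′ signal, a sign of RNA integrity, was compared among arrays. The log2 ratio of the 3′ to the 5′ Gapdh control signals was highest in Runx1KO replicate 3 (2.13) and control replicate 2 (1.85) and lay between 0.98 and 1.29 in the other 7. These 2 arrays also stood apart at the ends of the second principal component (20.8% of the variance), at 27.0 and -36.4 with the other 7 between -13.6 and 11.7. In the F test 421 of the 12393 genes differed among the 3 groups at an adjusted p under 0.05. That count was 228 without RUNX1(41-214) replicate 1, 207 without RUNX1(41-214) replicate 2 and 682 with array weights.

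The Runx1KO and control cells were compared to find which transcripts change when Runx1 is deleted. The mast cell protease gene Cpa3 and 3 of 20 megakaryocyte and platelet genes rose in Runx1KO cells, as did 4 of 28 niche adhesion and homing genes, a list whose call did not hold (adjusted p = 0.0735 with an estimated correlation). Treml1, a receptor of platelet granules, was at 9.71 ± 0.10 in Runx1KO against 7.04 ± 0.26 in control cells (log2 signal, SD, n = 3 each), a log2 fold change of 2.67 ± 0.22 (SE). Gp5, a subunit of the platelet receptor for von Willebrand factor, rose by 2.08 ± 0.19, and Itga2b, the integrin chain CD41 of megakaryocytes and early progenitors, rose by 1.29 ± 0.15. Fewer genes fell, among them the interleukin 1 receptor Il1r1 (-2.21 ± 0.36) and the thymus-homing chemokine receptor Ccr9 (-1.74 ± 0.29), both members of the early lymphoid list.

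In this comparison 43 genes passed the threshold, 29 higher and 14 lower in Runx1KO, and 895 genes had an unadjusted p under 0.05. Each of the 43 had arrays that did not overlap between the groups, as did 10.5% of all genes, where chance gives 10%. Beside Treml1 and Gp5, the largest rises were those of Cpa3 (3.04 ± 0.28, adjusted p = 0.000467), the keratin Krt80 (2.76 ± 0.22), the tight junction scaffold Tjp1 (2.68 ± 0.23) and the lymphoid GTPase Gimap4 (2.62 ± 0.23). They were followed by the chromatin protein Hmga2 (2.26 ± 0.26), the protocadherin Pcdh7 (2.18 ± 0.27), the sodium, calcium and potassium exchanger Slc24a3 (2.14 ± 0.27) and the receptor phosphatase Ptprm (2.10 ± 0.38, adjusted p = 0.0454). Among genes above the median signal (higher group mean above the median of all genes), those that fell besides Il1r1 and Ccr9 were Gcsam (-1.82 ± 0.27), the gap junction gene Gja1 (-1.70 ± 0.30), the Wnt inhibitor Apcdd1 (-1.70 ± 0.29) and Serpinf1 (-1.43 ± 0.26). With the mean of a gene's probe sets Ccr9 was at -1.20 and Serpinf1 at -0.84, and neither passed. Ptprm and Gzmb, with 1 probe set each and unchanged folds, did not pass either. With array weights these 2, Gcsam, Gja1, Serpinf1, Mllt3 and Tek did not pass. Runx1 itself was at 11.45 ± 0.27 in Runx1KO and 10.40 ± 0.45 in control cells, a log2 fold change of 1.05 ± 0.21 that did not pass (adjusted p = 0.0740). Of its other probe sets, the brighter ones were at 1.58 and 1.03 and did not pass either. Since neither the deleted exon nor the position of the probes along the transcript was known here, the Runx1 signal does not test the deletion.

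Of the gene lists, 8 passed the camera test in Runx1KO against control, 6 upward and 2 downward. The megakaryocyte and platelet list was higher (mean log2 fold change 0.55, adjusted p = 5.70e-08, adjusted p = 0.0415 with an estimated correlation). In all, 16 of 20 measured members lay above control. Of these, 3 passed over all genes (Treml1, Gp5 and Itga2b) and 6 passed adjusted over the list alone. Pf4, an abundant chemokine of platelets that was chosen after its values were seen, was at -0.07 ± 0.27 (adjusted p = 0.989). The niche adhesion and homing list was higher by 0.34 (adjusted p = 6.36e-08, adjusted p = 0.0735 with an estimated correlation), and 4 of its 28 members rose: Itga2b, the junctional adhesion molecule Jam3 (1.59 ± 0.21), the leukocyte integrin chain Itgb2 (1.00 ± 0.16) and Tek, the angiopoietin receptor of stem cells (1.21 ± 0.22). Adjusted over the list alone, 9 rose.

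The HSC-associated list was higher by 0.28 in Runx1KO (adjusted p = 0.00146, adjusted p = 0.313 with an estimated correlation). In it Mllt3, a regulator of stem cell maintenance, rose by 1.40 ± 0.23 together with Tek, and 5 rose and 1 fell adjusted over the list alone. Hox and self-renewal factors were higher by 0.23 (adjusted p = 0.0223, adjusted p = 0.362 with an estimated correlation). Hmga2 was the 1 member that passed, also when adjusted over the list alone. Runx family and partner factors were higher by 0.20 (adjusted p = 0.00117, adjusted p = 0.0867 with an estimated correlation) with 0 members past the threshold over all genes and 1 adjusted over the list alone. Immediate early and stress genes were higher by 0.30 (adjusted p = 0.00575, adjusted p = 0.417 with an estimated correlation), again with 0 members past the threshold. In this list Btg2 was at 0.90 ± 0.28 and Dusp1 at 0.57 ± 0.22. The T and NK cell list was lower (-0.34, adjusted p = 0.00247, adjusted p = 0.0867 with an estimated correlation), with the granzyme Gzmb, a gene below the median signal, down (-1.26 ± 0.23) and 4 members lower adjusted over the list alone. Its call was lost without dim genes. Ribosome biogenesis genes were lower by a small amount (-0.15, adjusted p = 0.0136, adjusted p = 0.313 with an estimated correlation), 20 of 23 below control and 0 past the threshold. The other 14 lists did not pass (adjusted p from 0.0600 to 0.958). When some single array was left out 9 of them did, among them the cell cycle and early lymphoid lists. The 14 included the reported Runx1 targets (0.25, adjusted p = 0.0633), where Hmga2 and Itga2b rose and Gzmb fell, and the cell cycle list (-0.05, adjusted p = 0.331).

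The count of 43 (14 lower) was 9, all higher, when only the 6 arrays of these groups were fitted, 18 (2 lower) with a minimum fold of 1.2, 21 (2 lower), 50 (23 lower) and 20 (3 lower) without control replicates 1, 2 and 3, 28 (6 lower), 22 (1 lower) and 14 (1 lower) without Runx1KO replicates 1, 2 and 3, and 25 (6 lower), 27 (9 lower) and 29 (6 lower) without RUNX1(41-214) replicates 1, 2 and 3. Of the 22 named genes past the threshold, 12 lost their call in at least 1 such omission (Ptprm, Il1r1, Gcsam, Ccr9, Gja1, Apcdd1, Serpinf1, Mllt3, Tek, Jam3, Itgb2 and Gzmb, adjusted p up to 0.197 for Gzmb without Runx1KO replicate 2), Gja1, Serpinf1 and Tek in all 9. So did the lists of immediate early genes (mean 0.10 to 0.47, adjusted p = 0.302 without control replicate 2, 0.158 without Runx1KO replicate 1), Hox factors (mean 0.15 to 0.32, adjusted p = 0.226 without Runx1KO replicate 2) and ribosome biogenesis (mean -0.19 to -0.09, adjusted p = 0.214 without control replicate 2, 0.0540 without Runx1KO replicate 2).

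RUNX1(41-214) cells were compared with control cells to find which transcripts accompany expression of the fragment. Of the early lymphoid genes 7 of 19 fell and of the B cell genes 3 of 16, and the call of neither list held (adjusted p = 0.305 and 0.491 with an estimated correlation). The interleukin 7 receptor Il7r was at 5.69 ± 0.29 against 9.38 ± 1.14 in control (log2 signal, SD, n = 3 each). Dntt, the terminal transferase of lymphoid progenitors, fell by 1.93 ± 0.24 (SE) and Notch1 fell by 1.67 ± 0.16. Of the megakaryocyte and platelet genes 7 of 20 rose, with Treml1 up by 3.38 ± 0.22, Gp5 by 2.43 ± 0.19, the adhesion receptor P-selectin (Selp) by 2.09 ± 0.18 and Itga2b by 2.02 ± 0.15. The largest single differences were the falls of Gdpd3, a lipid phosphodiesterase gene, and of Ndn, an imprinted growth suppressor, by 5.51 ± 0.18 and 5.19 ± 0.19.

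**Figure D1:**
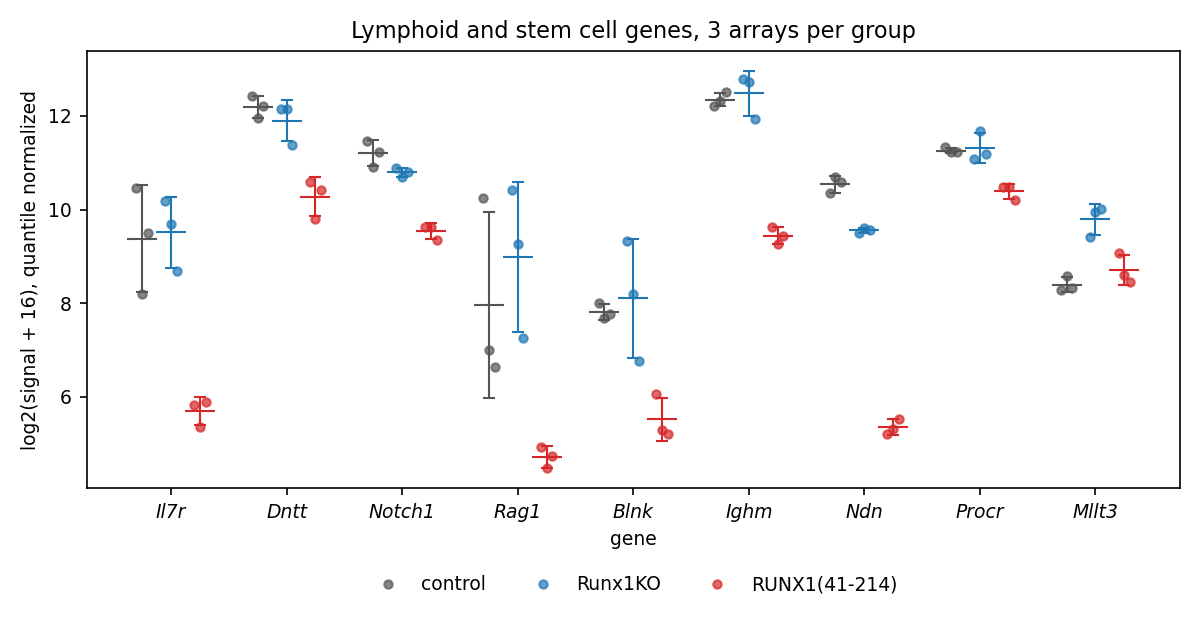
Log2(signal + 16) after quantile normalization of 9 lymphoid and stem cell genes, each point 1 array and each bar the group mean with its SD (n = 3 arrays per group). Il7r, Dntt, Notch1, Blnk, Ighm, Ndn and Procr, each on its brightest probe set, were lower in all 3 RUNX1(41-214) arrays than in every control and Runx1KO array, and the Runx1KO mean of Mllt3 lay 1.40 above control.

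In this comparison 531 genes passed the threshold, 214 higher and 317 lower in RUNX1(41-214), with 1918 at an unadjusted p under 0.05. Of the 531, 530 had arrays that did not overlap between the groups, as did 20.3% of all genes, where chance gives 10%. The largest rises were those of the lysosomal galactosylceramidase Galc (4.22 ± 0.19, adjusted p = 2.78e-07), Gimap4 (3.86 ± 0.23), the histidine decarboxylase Hdc (3.80 ± 0.58) and Cpa3 (3.77 ± 0.28). Next came the chemokine receptor Cxcr2 (3.40 ± 0.37), Treml1, the interferon-inducible Ifi209 (3.29 ± 0.45), Pcdh7 (3.01 ± 0.27), Shisa2 (2.97 ± 0.46) and the extracellular matrix gene Ecm1 (2.95 ± 0.23). The other probe sets of Galc, both dim, were at -0.05 and -0.16 against control and at 0.27 and -0.33 against Runx1KO. Besides Gdpd3, Ndn, Il7r (-3.69 ± 0.51) and Ighm (-2.91 ± 0.20), the immunoglobulin heavy chain gene, the largest falls among genes above the median signal were those of the guanylate-binding protein Gbp2b (-4.63 ± 0.32), Bex1 (-3.99 ± 0.34), the sialyltransferase St6gal1 (-3.36 ± 0.51), Bex4 (-3.02 ± 0.29), Gja1 (-2.91 ± 0.30) and Zcchc18 (-2.87 ± 0.29). The other probe set of St6gal1, a dimmer one, was at 0.11. Runx1 was at 10.94 ± 0.12 against 10.40 ± 0.45 and did not pass (0.55 ± 0.21, adjusted p = 0.223). Of its other probe sets, the brighter ones were at 1.38 and 1.07, and the latter passed when all probe sets were tested (adjusted p = 0.0291).

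The early lymphoid list was lower in RUNX1(41-214) by a mean of 1.06 (mean log2 fold change -1.06, adjusted p = 5.21e-07, adjusted p = 0.305 with an estimated correlation): 7 of its 19 measured members fell and 1 rose, and 9 fell and 1 rose adjusted over the list alone. Il7r, Dntt, Notch1 and Ccr9 (-2.18 ± 0.29) had the 4 smallest p-values, and the member that rose was Cd52, a surface glycoprotein of lymphocytes that was named after its values were seen (1.08 ± 0.20). The gate excluded cells with surface IL7Ra, and the Il7r mRNA of the control cells was measured within it. The B cell list was lower on average (-0.81, adjusted p = 0.0155, adjusted p = 0.491 with an estimated correlation). Its median was -0.21, with 10 of 16 members lower and 6 higher. Ighm, the adaptor Blnk (-2.31 ± 0.50) and the surrogate light chain Vpreb1 (-1.54 ± 0.39) were the 3 of 16 that fell, and 5 were lower and 1 higher adjusted over the list alone. The fall of Ighm was seen in its brighter probe sets (-2.91 and -2.80) but not in the next ones (0.01 and 0.35), and the mean of its probe sets, -0.52, did not pass. Cd24a, the brightest B cell gene beside Ighm, was at 0.02 ± 0.10. T and NK cell genes were lower on average (-0.43, adjusted p = 0.0296, adjusted p = 0.220 with an estimated correlation). Their median was -0.08, and the call was lost without dim genes. Of 18 members, 5 fell, among them the cytotoxic granule gene Nkg7 (-2.43 ± 0.34), Gzmb (-1.37 ± 0.23), Gzma (-0.99 ± 0.22) and Bcl11b (-2.16 ± 0.53), with 5 lower and 1 higher adjusted over the list alone.

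The megakaryocyte and platelet list was higher by 0.95 (adjusted p = 1.76e-09, adjusted p = 0.0415 with an estimated correlation). Of 20 members, 18 lay above control, 7 were past the threshold and 10 passed adjusted over the list alone. Its brightest members, the thrombin receptor F2r (0.69 ± 0.16) and pleckstrin, Plek (0.83 ± 0.18), were among the 7. Pf4 was at 0.76 ± 0.27 and Ppbp, another platelet chemokine chosen after its values were seen, at 2.03 ± 0.64, and neither passed (adjusted p = 0.169 and 0.125). Niche adhesion and homing genes were higher by 0.45 (adjusted p = 4.68e-06, adjusted p = 0.0867 with an estimated correlation): 8 of 28 rose, led by Itga2b, Selp, Jam3 (2.00 ± 0.21) and Tek (1.59 ± 0.22), and 1 fell, against 11 higher and 1 lower adjusted over the list alone. The interferon-stimulated list was higher by 0.24 (adjusted p = 0.0473, adjusted p = 0.633 with an estimated correlation), with Ifi27l2a (1.23 ± 0.28) and Ifi47 (0.34 ± 0.08) past the threshold and 3 adjusted over the list alone.

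**Figure D2:**
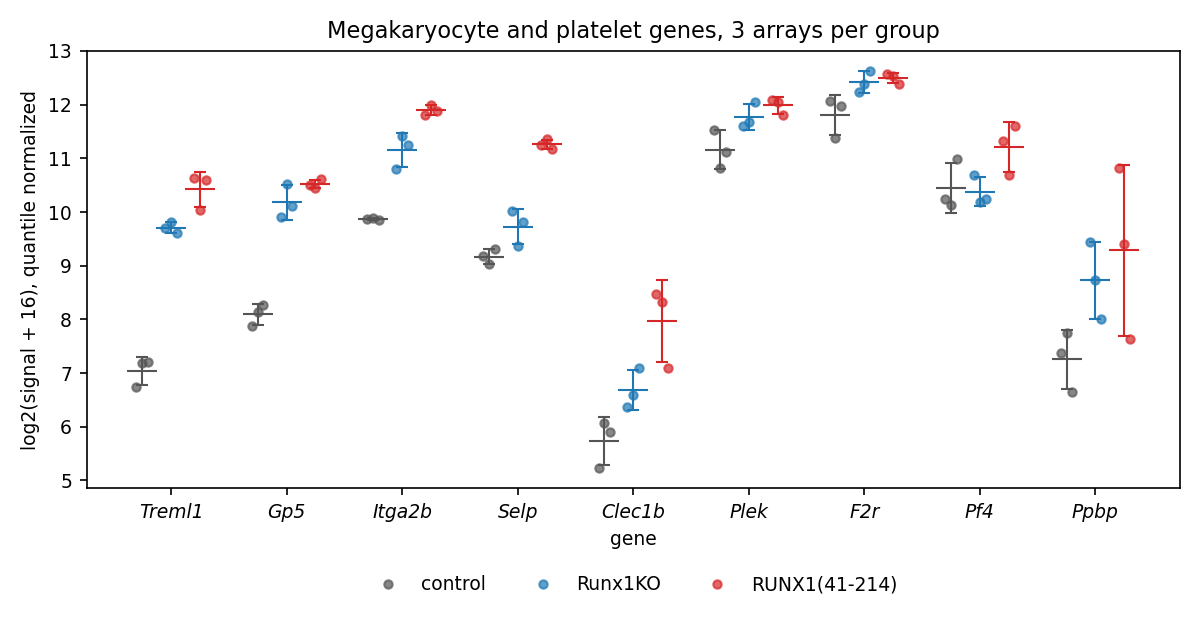
Log2(signal + 16) after quantile normalization of 9 megakaryocyte and platelet genes, each point 1 array and each bar the group mean with its SD (n = 3 arrays per group). All Runx1KO and RUNX1(41-214) arrays lay above all control arrays for Treml1, Gp5 and Itga2b, whereas the control and Runx1KO arrays overlapped for Pf4, which like Ppbp and Clec1b was chosen after its values were seen.

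The other 16 lists did not pass in RUNX1(41-214) against control (adjusted p from 0.0530 to 0.971), although some of their members did. With some single array left out, 6 of these lists passed. In the HSC-associated list (-0.38, adjusted p = 0.0905) Tek rose and 5 members fell, among them Ndn, the endothelial protein C receptor Procr (-0.87 ± 0.16) and Ltb (-1.20 ± 0.23). In the mast cell and basophil list (0.65, adjusted p = 0.132) Cpa3, Hdc and the IgE receptor chain Ms4a2 (1.72 ± 0.24) rose and Gzmb fell. In the erythroid list (0.04, adjusted p = 0.958) the haem synthesis gene Alas2 (2.20 ± 0.41) and the red cell anion exchanger Slc4a1 (2.91 ± 0.55) rose and the transferrin receptor Tfrc fell by 0.75 ± 0.18. The granulocyte list (0.33, adjusted p = 0.0697) had Csf3r up by 0.71 ± 0.18, and in the monocyte, macrophage and dendritic cell list (-0.21, adjusted p = 0.311) the chemokine receptor Ccr2 (-2.69 ± 0.35), Mpeg1 (-2.20 ± 0.47) and Cd74 (-0.93 ± 0.23) fell. Egr1 (-1.24 ± 0.21) fell and Ier2 (0.88 ± 0.19) rose in the immediate early list (-0.07, adjusted p = 0.867). Myc rose by 0.83 ± 0.18, and Hoxb2 (-1.66 ± 0.35) and Hoxa9 (-0.54 ± 0.12) fell in the Hox list (-0.03, adjusted p = 0.769). The cell cycle inhibitor Cdkn1b rose by 0.90 ± 0.15 on its brighter probe set, but the mean of its probe sets gave -0.30 and did not pass. With that mean Hoxa9 (-0.46) and Tfrc (-0.62) did not pass either. Nor did Csf3r, Bcl11b and Vpreb1, which have 1 probe set each and kept their folds.

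The count of 531 (214 higher, 317 lower) was 352 without control replicate 3, 298 and 297 without RUNX1(41-214) replicates 1 and 2, and 294 with a minimum fold of 1.2. Of the 56 named genes past the threshold, 17 lost their call when some single array was left out (Ltb, Alas2, Slc4a1, Tfrc, Csf3r, Mpeg1, Cd74, Blnk, Vpreb1, Gzma, Bcl11b, Ifi27l2a, Ifi47, Ier2, Hoxb2, Myc and Hoxa9, adjusted p up to 0.206 for Csf3r without RUNX1(41-214) replicate 1), as did the B cell list (mean -0.92 to -0.64, adjusted p = 0.0638 without RUNX1(41-214) replicate 3, 0.0558 without control replicate 1) and the interferon-stimulated list (mean 0.12 to 0.36, adjusted p = 0.366 without RUNX1(41-214) replicate 1, 0.172 without control replicate 3, 0.0959 without RUNX1(41-214) replicate 3, 0.0691 without control replicate 2, 0.0503 without Runx1KO replicate 2).

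The changes against control were set side by side to ask whether loss of Runx1 and expression of the fragment move the same genes. Of the 43 genes that passed in Runx1KO, 41 also passed in RUNX1(41-214), 27 higher and 14 lower in both, and 0 passed in opposite directions. Krt80 (2.76 and 2.85), Treml1, Tjp1 (2.68 and 2.77), Gimap4, Cpa3, Gp5, Itga2b, Hmga2 (2.26 and 2.14), Pcdh7 and Slc24a3 (2.14 and 2.67) were the 10 shared genes with the smallest p-values. Of the 41 shared genes, 5 also differed between RUNX1(41-214) and Runx1KO (Gimap4, Itga2b, Ecm1, Nrk and Serpinf1, of which Nrk was named after its values were seen), each with the larger change in RUNX1(41-214).

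Independent lists of these sizes would share 0.501 higher and 0.358 lower genes, a figure that leaves out the effect of the shared control arrays. Over all genes the log2 fold changes of both comparisons had a Pearson r of 0.566, where shared controls alone gave 0.502, and a covariance of 0.0792 against 0.0261. Genes are not independent replicates, and no p is attached to these values. The count of 41 (14 lower) was 20 (2 lower), 47 (22 lower) and 20 (3 lower) without control replicates 1, 2 and 3, 25 (6 lower), 20 (1 lower) and 14 (1 lower) without Runx1KO replicates 1, 2 and 3, and 22 (6 lower), 24 (7 lower) and 26 (5 lower) without RUNX1(41-214) replicates 1, 2 and 3.

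**Figure D3:**
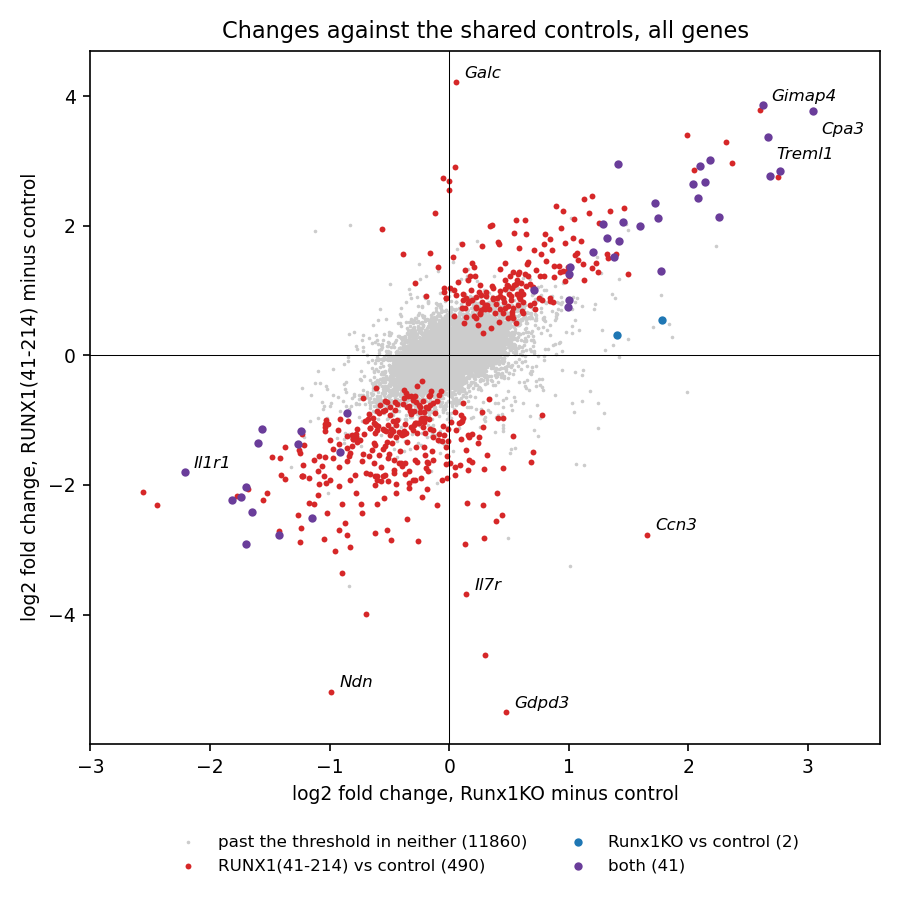
Log2 fold change of each of the 12393 genes in Runx1KO minus control (horizontal) and RUNX1(41-214) minus control (vertical), each from 3 arrays per group with the same control arrays. The 41 genes past the threshold in both lie at the upper right and lower left of the plot, while Galc, Gdpd3 and Il7r moved along the vertical axis, with Runx1KO values of 0.05, 0.47 and 0.14.

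RUNX1(41-214) and Runx1KO cells were compared directly to find where the fragment and the deletion differ. In cells with the fragment 5 of 21 HSC-associated, 5 of 19 early lymphoid and 4 of 16 B cell genes fell and 2 of 20 megakaryocyte and platelet genes rose. The calls of these 4 lists did not hold (adjusted p = 0.0915, 0.313, 0.305 and 0.0867 with an estimated correlation). Ndn was at 5.35 ± 0.16 in RUNX1(41-214) and 9.55 ± 0.05 in Runx1KO (log2 signal, SD, n = 3 each), Il7r fell by 3.83 ± 0.51 (SE), the recombinase gene Rag1 by 4.27 ± 0.89 and Ighm by 3.04 ± 0.20 on its brightest probe set. Selp rose by 1.53 ± 0.18 and Itga2b by 0.74 ± 0.15.

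In total 168 genes passed, 37 higher and 131 lower in RUNX1(41-214), with 1312 at an unadjusted p under 0.05. All 168 had arrays that did not overlap between the groups, as did 18.8% of all genes, where chance gives 10%. Among genes above the median signal, the largest falls were those of Gdpd3 (-5.98 ± 0.18, adjusted p = 9.72e-09), Gbp2b (-4.92 ± 0.32), the secreted matricellular gene Ccn3 (-4.42 ± 0.35), Rag1, Ndn (-4.20 ± 0.19) and Il7r. They were followed by Bex1 (-3.29 ± 0.34), the immunoglobulin joining chain Jchain (-3.11 ± 0.52), Ighm and the nuclear receptor Hnf4a (-2.60 ± 0.31). Under the same limit the largest rises were those of Galc (4.17 ± 0.19), Slc4a1 (2.86 ± 0.55), Ankrd33b (2.79 ± 0.30), Tmprss3 (2.51 ± 0.33), Riok2 (1.96 ± 0.24), Slc37a1 (1.66 ± 0.23), the Wnt receptor Fzd6 (1.65 ± 0.25), S100a6 (1.62 ± 0.20), Ecm1 (1.54 ± 0.23) and Selp. The other probe set of Riok2 was at 0.40 against Runx1KO and 0.45 against control and passed in neither when all probe sets were tested. Runx1 was lower by a difference that did not pass (-0.50 ± 0.21, adjusted p = 0.410), and the mean of its 5 probe sets gave 0.04.

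The HSC-associated list was lower in RUNX1(41-214) than in Runx1KO (-0.66, adjusted p = 1.72e-08, adjusted p = 0.0915 with an estimated correlation). Of 21 members, 19 lay lower, 5 were past the threshold and 8 passed adjusted over the list alone. Ndn, Procr (-0.92 ± 0.16), Sult1a1 (-2.19 ± 0.42) and the transglutaminase Tgm2 (adjusted p = 0.0280) fell. Early lymphoid genes were lower (-0.90, adjusted p = 6.36e-06, adjusted p = 0.313 with an estimated correlation): 5 of 19 fell, among them Notch1 (-1.26 ± 0.16), Il7r, Dntt (-1.62 ± 0.24) and Blnk (-2.59 ± 0.50), with 6 lower and 1 higher adjusted over the list alone. B cell genes were lower on average (-1.10, adjusted p = 4.49e-05, adjusted p = 0.305 with an estimated correlation), but 9 of 16 lay lower and 7 higher. The deposited signals of Pou2af1, Blnk and Rag1 varied widely among the Runx1KO arrays (263 ± 234, 341 ± 280 and 720 ± 636, SD, n = 3). Ighm, the coactivator Pou2af1 (-2.82 ± 0.50), Blnk and Rag1 were the 4 of 16 that fell, with 8 lower and 1 higher adjusted over the list alone. With the mean of a gene's probe sets Ighm was at -0.79, Ccr2 at -0.85 and Selp at 1.21, and these genes did not pass. Nor did Rag1, which has 1 probe set and kept its fold. Monocyte, macrophage and dendritic cell genes were lower (-0.50, adjusted p = 0.00391, adjusted p = 0.313 with an estimated correlation). In it Cd74 (-1.70 ± 0.23) and Ccr2 (-1.77 ± 0.35) fell, and 4 fell adjusted over the list alone. Hox and self-renewal factors were lower (-0.26, adjusted p = 0.0155, adjusted p = 0.329 with an estimated correlation) with 0 members past the threshold and 2 adjusted over the list alone.

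Megakaryocyte and platelet genes were higher in RUNX1(41-214) than in Runx1KO (0.39, adjusted p = 0.000313, adjusted p = 0.0867 with an estimated correlation), with Selp and Itga2b past the threshold and 5 adjusted over the list alone. Granulocyte genes were higher (0.55, adjusted p = 0.0296, adjusted p = 0.601 with an estimated correlation), 18 of 21 above Runx1KO, with 0 members past the threshold or adjusted over the list alone. The call was lost without dim genes (0.33) and with array weights (0.51). The member Ms4a3 was at 1.65 ± 0.57 and Prtn3 at 0.40 ± 0.16. The other 15 lists did not pass (adjusted p from 0.0517 to 0.958). Of these, 4 passed when some single array was left out. Among their members Egr1 (-1.19 ± 0.21) and the p53 target Plk2 (-1.76 ± 0.23) fell, and Alas2 (2.32 ± 0.41), Slc4a1 and Ms4a2 (1.30 ± 0.24) rose.

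**Figure D4:**
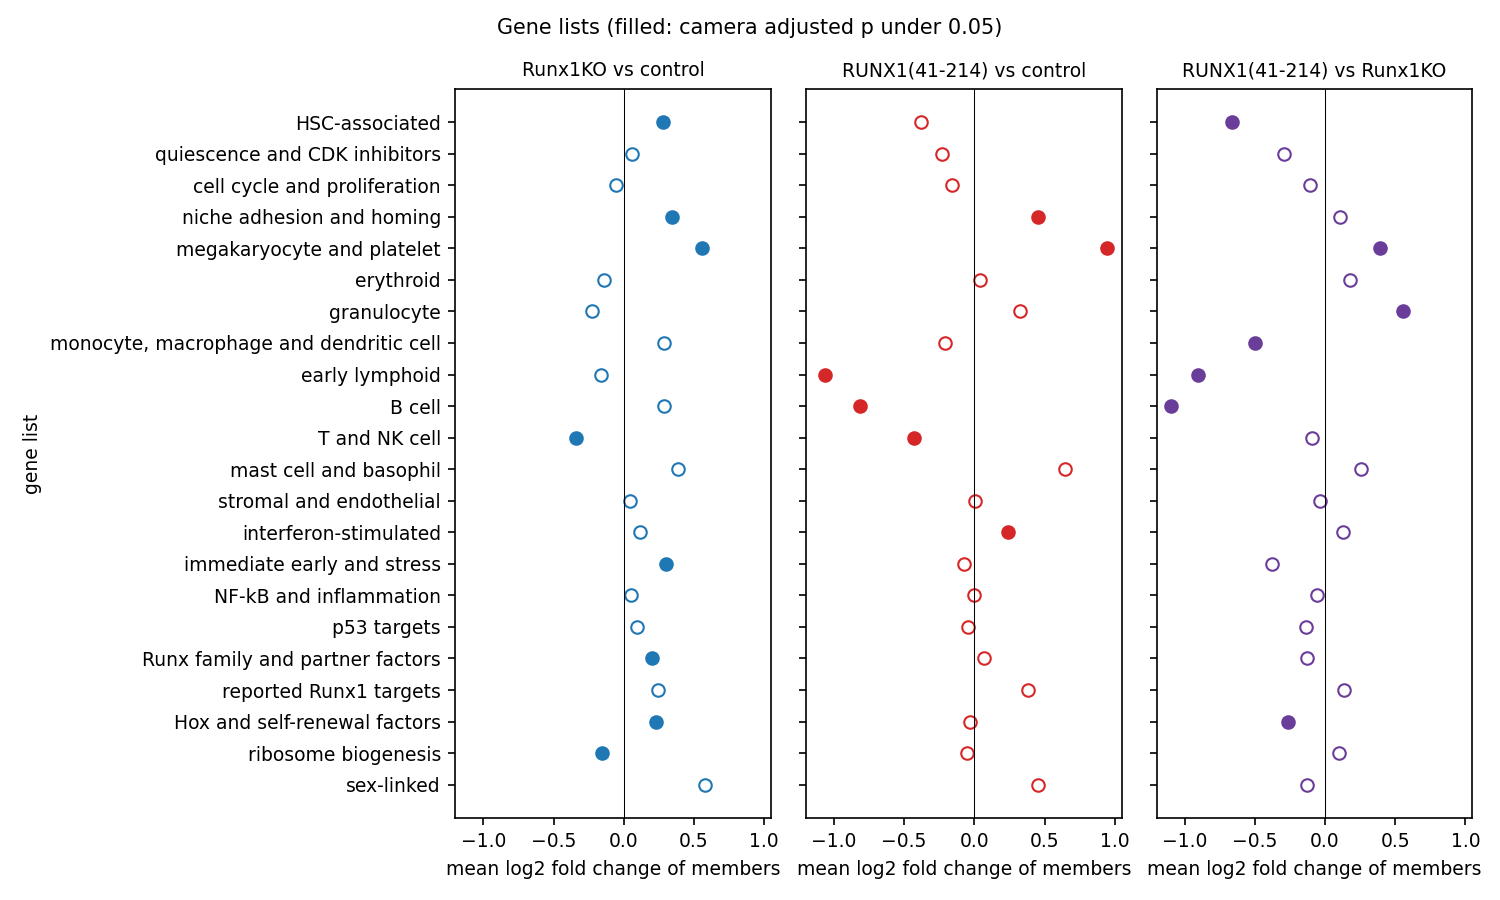
Mean log2 fold change over the measured members of the 22 gene lists in each of the 3 comparisons, filled points for lists with a camera adjusted p under 0.05 at a preset correlation of 0.01. The megakaryocyte and platelet list was higher in all 3 comparisons (0.55, 0.95 and 0.39, adjusted p = 0.0415, 0.0415 and 0.0867 with an estimated correlation), and the HSC-associated list lay above 0 in Runx1KO against control (0.28) and below 0 in RUNX1(41-214) against Runx1KO (-0.66), calls that did not hold (adjusted p = 0.313 and 0.0915 with an estimated correlation).

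The count of 168 was 92 without Runx1KO replicate 2, 91, 74 and 106 without RUNX1(41-214) replicates 1, 2 and 3, 90 with a minimum fold of 1.2 and 371 (129 higher, 242 lower) with array weights. Of the 34 named genes past the threshold, 14 lost their call when some single array was left out (Slc4a1, Fzd6, Rag1, Jchain, Procr, Sult1a1, Tgm2, Egr1, Itga2b, Alas2, Ccr2, Blnk, Pou2af1 and Ms4a2, adjusted p up to 0.208 for Itga2b without RUNX1(41-214) replicate 2), as did the granulocyte list (mean 0.24 to 0.80, adjusted p = 0.277 without RUNX1(41-214) replicate 1, 0.264 without Runx1KO replicate 2, 0.0634 without Runx1KO replicate 3) and the Hox list (mean -0.35 to -0.18, adjusted p = 0.0968 without Runx1KO replicate 2).

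Across the 3 comparisons 21 of the 66 pairs of list and comparison passed with the preset correlation, 2 passed with an estimated one (the megakaryocyte and platelet list in both comparisons against control). Fry, which does not compare a list with other genes, called 13, and of 100 splits of the 9 arrays into 3 groups, the real one included, 14 gave at least 21 camera calls. The median, the mean and the test differed in sign in 9 of the 66 pairs, of which 0 passed: early lymphoid and mast cell genes in Runx1KO against control; quiescence, erythroid, mast cell, immediate early and Hox genes in RUNX1(41-214) against control; and T and NK cell and stromal genes in RUNX1(41-214) against Runx1KO. The lists overlap: 10 of the 20 measured megakaryocyte genes, 10 of the 28 niche adhesion genes, 11 of the 21 HSC-associated genes, 4 of the 19 early lymphoid genes and 5 of the 16 B cell genes are also on another list. In control cells 13 of the 20 megakaryocyte, 13 of the 19 early lymphoid, 4 of the 16 B cell and 2 of the 18 T and NK cell genes lay above the median of all genes, which is not a limit of detection.

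The brightest genes of the lists of other cell types were compared. Whether their signal comes from such cells or from the KSL cells themselves was not tested, so that they do not measure carried-over cells. Of these genes, Cpa3 of mast cells rose by 3.04 in Runx1KO and by 3.77 in RUNX1(41-214). In RUNX1(41-214) also Nkg7, Ighm and Tfrc fell (-2.43, -2.91 and -0.75) and F2r and Plek rose (0.69 and 0.83). The other probe set of F2r, also bright, was at 1.17 in Runx1KO and 1.80 in RUNX1(41-214) and passed in both when all probe sets were tested, where the brightest did not. The granulocyte enzyme Mpo was at 12.25 ± 0.36 in control, 12.52 ± 0.32 in Runx1KO and 12.41 ± 0.19 in RUNX1(41-214) (log2 signal, SD, n = 3 each). The carbonic anhydrase Car2 of red cells was at 12.48 ± 0.31, 12.56 ± 0.08 and 12.42 ± 0.04, and Anxa1 at 11.83 ± 0.07, 11.89 ± 0.05 and 11.92 ± 0.03 in the same order. The monocyte genes Cst3 and Ctss differed from control by 0.14 ± 0.11 and -0.15 ± 0.29 in Runx1KO and by 0.40 ± 0.11 and -0.57 ± 0.29 in RUNX1(41-214), none past the threshold. Gata3 of T cells (0.58 ± 0.25 and -0.05 ± 0.25), Mitf of mast cells (0.13 ± 0.30 and -0.11 ± 0.30) and the stromal genes Bgn (0.29 ± 0.20 and -0.31 ± 0.20) and Pdgfrb (-0.07 ± 0.22 and -0.03 ± 0.22) did not pass either.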

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

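The tests of the sequence flanking Runx1, of platelets, of the share of lymphoid-primed cells and of genes without another bright probe set were chosen after the result was seen.

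In 7 lists and a group of genes the effects against control differed between RUNX1(41-214) and Runx1KO. The mean difference was 0.39 for the megakaryocyte and platelet list, -0.90 for early lymphoid genes, -0.66 for the HSC-associated list, 0.55 for granulocyte genes, -0.50 for monocyte, macrophage and dendritic cell genes, -1.10 for B cell genes and -0.26 for Hox and self-renewal factors. These rest on a preset correlation, and with an estimated correlation their adjusted p was 0.0867, 0.313, 0.0915, 0.601, 0.313, 0.305 and 0.329 in that order. Of 100 splits of the 9 arrays into 3 groups, 14 gave at least the 21 list calls of the real one, with a highest of 26 and a median of 14, so that chance cannot be excluded for the number of list calls. In 85 genes the effects had opposite signs and differed past the threshold, 67 of them lower and 18 higher in RUNX1(41-214) than in control. Among them were Gdpd3, Gbp2b, Ighm and Ccn3, and 54 passed in RUNX1(41-214) against control and 0 in Runx1KO against control, where limma gave 895 genes at an unadjusted p under 0.05. With 0 of them past the threshold in Runx1KO, opposed effects are not shown, and some Runx1KO effects lay near 0, as that of Procr (0.05). Among the probe sets without a single gene name, which the gene counts do not use, 54 passed in RUNX1(41-214) against control, 22 in RUNX1(41-214) against Runx1KO and 0 in Runx1KO against control, of 2246.

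Expression in RUNX1(41-214) differed from both other groups in 134 genes, 31 higher and 103 lower. Sequence differences confined to a single probe set were argued against where another bright probe set existed. A sequence difference shared by several probe sets of a gene was not tested. Of 36 such probe sets, 88.9% had the same sign in both differences (exact 95% interval 73.9 to 96.9%). They belong to 23 genes and are not independent. Counted by the brightest other probe set of each gene, 21 of 23 had the same sign (exact 95% interval 72.0 to 98.9%). Only the sign was counted, also where a difference was near 0, as in Ccr2 (-0.39 against control and -2.41e-05 against Runx1KO). The other 111 genes had no such probe set and stay open. For RNA quality, 4 of the 6 Gapdh and Actb ratios of the RUNX1(41-214) arrays lay inside the range of the other arrays. The range of the other arrays is stretched by the Gapdh log2 ratios of Runx1KO replicate 3 (2.13) and control replicate 2 (1.85). The values therefore show only that the RUNX1(41-214) arrays were not set apart in these ratios, and a smaller difference stays open. Segments of another strain in the floxed mice stay open: 4 adjacent pairs of genes passed against a median of 1 in random draws (permutation p = 0.0628), and the genes beside Runx1 had a one-sided Fisher exact p of 0.235 (2 of 85 against 132 of 12291). The fragment, the biological difference the design names, remains an untested explanation beside these.

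Early lymphoid and B cell genes were lower in RUNX1(41-214) than in control, 7 of 19 and 3 of 16 members past the threshold, and the call of neither list held (adjusted p = 0.305 and 0.491 with an estimated correlation). Fewer lymphoid-primed cells in the gate stay open as an explanation: 81.8% of the 11 early lymphoid genes above the median of all genes lay below control, 4 of them past the threshold, while Cd52 rose by 1.08 ± 0.20. A single gene seen before the test was written excludes nothing. The effects of transplantation, of transduction and of poly IC, which the labels do not name for this group, cannot be told apart from that of the fragment. Arrays labelled as transplanted vector-only or poly IC-treated RUNX1(41-214) mice numbered 0 here.

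The megakaryocyte and platelet genes were higher in both Runx1KO and RUNX1(41-214). Platelets or megakaryocytes carried along in the sorted cells stay open: of the 4 values of Pf4 and Ppbp, 2 (those of Pf4, -0.07 and 0.76) lay more than 2 SE below the median of the members that passed (2.08 and 2.09), and those of Ppbp (1.48 and 2.03) did not. The gate excluded lineage-positive cells, but whether it removed platelets or megakaryocytes was not tested. Deletion of Runx1 and expression of the fragment are the biological differences the design names, and neither was tested further as a cause.

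The counts were set beside other splits of the arrays. For each pair of groups 10 splits of 6 arrays exist, too few for a share under 0.05: 1 of 10 reached the 43 genes of Runx1KO against control (highest other 4), 1 of 10 the 531 of RUNX1(41-214) against control (highest other 7) and 1 of 10 the 168 of RUNX1(41-214) against Runx1KO (highest other 0). Of 100 of the 280 splits of the 9 arrays, 1, the real one, reached the 421 genes of the F test. That is the smallest share that 100 splits can give, so that a count this high was rare among them but chance is not excluded. The next highest gave 201 and 183, and both kept the 3 RUNX1(41-214) arrays together. The count therefore rests largely on that group, whose treatment differed in more than the fragment. For the 41 shared genes 2 of 100 splits reached the count, the real split included, and the highest other gave 94. That split set the 3 RUNX1(41-214) arrays as the reference for mixed groups of control and Runx1KO arrays, and points to the distance of these arrays from the other 6. Shared reference arrays can therefore give more shared genes than the real groups did, and chance is not excluded for this count.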

How the results depend on the processing

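The omission of Runx1KO replicate 3 and control replicate 2 together, the arrays with the highest Gapdh ratios, was chosen after seeing the data, and the other alternatives were fixed in advance. Of 3272 values of named genes under the alternatives, 2926 kept direction and side of the threshold, 307 lost the threshold, 33 gained it and 6 reversed, 1 of them of a gene that had passed. For the lists, 1183 of 1386 kept both, 65 lost the threshold, 75 gained it and 63 reversed in the direction of the test, 0 of them of a list that had passed. The mean over a list is printed below and can keep its sign where the test's direction turned. With 1 array left out, the counts ran from 14 to 50 genes in Runx1KO against control, 297 to 612 in RUNX1(41-214) against control, 74 to 207 in RUNX1(41-214) against Runx1KO, 207 to 452 in the F test and 14 to 47 for the shared genes. A group then has 2 arrays, and the spread comes from all groups. Array weights gave 33 genes (26 higher, 7 lower) in Runx1KO against control, 371 (129 higher, 242 lower) in RUNX1(41-214) against Runx1KO and 682 in the F test. In Runx1KO against control, the test of all probe sets gave 31 probe sets (25 higher, 6 lower) and no variance trend gave 38 genes (22 higher, 16 lower). A minimum fold of 1.2 gave 18, 294 and 90 genes in the 3 comparisons, by its construction fewer. Only the 6 arrays compared gave 9, 443 and 175 genes in the 3 comparisons, against 43, 531 and 168 with all 9 arrays. All 3 fits had fewer residual degrees of freedom, but only the count of Runx1KO against control fell this far. With all 9 arrays the spread also comes from the third group, and which of these lowered the count was not tested. An estimated correlation left 2 list calls and fry gave 13. With the 2 arrays left out the counts were 32, 768 and 130. Of the named genes 19 values then lost the threshold and 1 gained it, and of the lists 5 lost it and 4 gained it. The block for replicate numbers, which the main fit did not treat as pairs, gave 48, 539 and 171, and an offset of 1 gave 38 (30 higher, 8 lower), 529 and 181. The gene values that reversed came from the mean of a gene's probe sets, in Cdkn1b (-0.30) in RUNX1(41-214) against control and in Runx1 (0.0376), Cbfa2t3 (0.00144) and Ubtf (-0.11) in RUNX1(41-214) against Runx1KO, and from single omissions in Kdm5d in RUNX1(41-214) against Runx1KO (-0.47 to 0.0720). In the lists of Runx1KO against control, the mean was 0.0692 for cell cycle, 0.0787 for erythroid and -0.10 for granulocyte genes with array weights, 0.0552 for granulocyte genes without dim genes and -0.31 for them with an offset of 1. With the 2 arrays left out it was 0.23 for cell cycle, 0.40 for erythroid, -0.0396 for monocyte, macrophage and dendritic cell, -0.13 for p53 target and -0.0782 for quiescence genes. In RUNX1(41-214) against control it was -0.0347 for erythroid genes with array weights, -0.26 for quiescence and -0.0495 for stromal genes without quantile normalization, and -0.23 for quiescence genes with only the 6 arrays. Without dim genes it was 0.12 for Hox, 0.0571 for NF-kB, -0.36 for erythroid and -0.25 for stromal genes, and with the mean of probe sets 0.0731 for Hox and -0.0331 for erythroid genes. With the 2 arrays left out it was 0.00761 for cell cycle, -0.26 for immediate early, 0.0141 for ribosome biogenesis and 0.0190 for stromal genes. In RUNX1(41-214) against Runx1KO it was -0.11 for erythroid and 0.0139 for stromal genes with array weights, -0.17 for erythroid genes without dim genes and 0.0298 for them with the 2 arrays left out. With single arrays left out, the means in Runx1KO against control ran from -0.55 to 0.25 for erythroid, -0.25 to 0.11 for cell cycle, 0.0161 to 0.0668 for stromal, -0.38 to 0.0781 for early lymphoid, -0.58 to 0.22 for granulocyte, -0.0456 to 0.17 for p53 target and -0.0300 to 0.12 for quiescence genes. In RUNX1(41-214) against control they ran from -0.37 to 0.43 for erythroid, -0.39 to 0.00782 for cell cycle, -0.0422 to 0.0583 for stromal, -0.26 to 0.0898 for immediate early and -0.32 to -0.17 for quiescence genes. In RUNX1(41-214) against Runx1KO they ran from -0.12 to 0.36 for erythroid, -0.33 to 0.0157 for cell cycle, -0.0836 to 0.0166 for stromal, -0.15 to -0.0408 for T and NK cell, 0.00832 to 0.24 for interferon-stimulated and -0.28 to 0.0483 for sex-linked genes. Some lists that had not passed did so with a single array left out, with adjusted p over the 9 omissions as follows. In Runx1KO against control it ran from 0.0122 to 0.820 for cell cycle, 0.0143 to 0.961 for erythroid and 0.00315 to 0.751 for monocyte, macrophage and dendritic cell genes. It ran from 0.00474 to 0.994 for early lymphoid and 0.000175 to 0.829 for B cell genes. It ran from 0.0368 to 0.751 for mast cell, 0.0132 to 0.624 for interferon-stimulated, 0.0250 to 0.454 for reported Runx1 target and 0.00121 to 0.231 for sex-linked genes. The range in RUNX1(41-214) against control was 0.0401 to 0.169 for HSC-associated, 0.000725 to 0.987 for cell cycle and 0.000496 to 0.751 for granulocyte genes. It was 0.0308 to 0.445 for mast cell, 0.0143 to 0.280 for reported Runx1 target and 0.0292 to 0.544 for sex-linked genes. The range in RUNX1(41-214) against Runx1KO was 0.0477 to 0.430 for quiescence and 0.00154 to 0.849 for cell cycle genes. It was 0.0302 to 0.916 for interferon-stimulated and 0.00935 to 0.325 for immediate early genes. With all 9 arrays, calls of genes were lost as follows in the 3 comparisons in turn. Array weights lost Ptprm, Gcsam, Gja1, Serpinf1, Mllt3, Tek and Gzmb. No variance trend lost Ptprm, Serpinf1, Tek and Gzmb, then Tfrc, Csf3r, Vpreb1, Bcl11b, Ifi47 and Hoxa9, then Rag1, Tgm2 and Itga2b. The replicate block lost Ptprm, Ccr9, Serpinf1, Mllt3 and Tek, then Tfrc, Cd74 and Ifi47. Offsets of 1 or 50 lost Ptprm, Gja1, Serpinf1 and Gzmb, then Vpreb1 and Bcl11b, then Slc4a1, Rag1 and Blnk. Values without quantile normalization lost Serpinf1, then Csf3r. The test of all probe sets lost Ptprm, Il1r1, Ccr9, Gja1, Apcdd1, Serpinf1, Mllt3, Tek and Gzmb, then Tfrc, Csf3r, Cd74, Vpreb1, Bcl11b and Ifi47, then Rag1. Of the lists, array weights lost Hox and ribosome biogenesis in Runx1KO, B cell and interferon-stimulated in RUNX1(41-214), and granulocyte and Hox genes between them. Leaving out dim genes lost T and NK cell genes in both, interferon-stimulated genes in RUNX1(41-214), and granulocyte and Hox genes between them. The mean of probe sets lost B cell genes in RUNX1(41-214) and Hox genes between them, and the replicate block lost interferon-stimulated genes in RUNX1(41-214). Except where the construction is named, the cause was not tested. Dim genes lie near the offset of 16, which limits the fold that can be seen in them.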

Other observations

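The genes of the sorting markers and of related stem cell markers were chosen after their values were seen. Kit, the receptor used in the gate, was at 11.15 ± 0.15 in control, 11.64 ± 0.20 in Runx1KO and 11.72 ± 0.18 in RUNX1(41-214) (log2 signal, SD, n = 3 each), and it rose in RUNX1(41-214) against control by 0.57 ± 0.14 (SE). Cd34 differed from control by 0.03 ± 0.11 and 0.23 ± 0.11, Flt3 by -0.41 ± 0.20 and -0.60 ± 0.20, and Slamf1 by 0.93 ± 0.29 and 0.79 ± 0.29 in Runx1KO and RUNX1(41-214), none past the threshold. The niche adhesion genes Itga6 (0.72) and Itga5 (1.28) rose and Alcam (-1.51) fell in RUNX1(41-214) against control, as did Thy1 (-1.07), and these genes were also chosen after their values were seen.

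Lists that did not pass had these mean log2 fold changes, with the members of smallest p beside them. In Runx1KO against control they were 0.06 for quiescence genes (Ndn -0.99 ± 0.19, adjusted p = 0.0580), -0.05 for cell cycle genes (E2f1 -0.53, Rrm2 -0.58), -0.14 for erythroid genes (Tfrc -0.39, Epb42 0.29) and -0.23 for granulocyte genes (Csf3r 0.72, Itgam 0.44). Monocyte, macrophage and dendritic cell genes were at 0.29 (Cd74 0.78, F13a1 2.23), early lymphoid genes at -0.16, B cell genes at 0.28 (Cd22 0.53, Pou2af1 1.13) and mast cell and basophil genes at 0.39. Stromal and endothelial genes were at 0.04 (Kdr 0.64, Lum -0.42), interferon-stimulated genes at 0.11 (Igtp 0.54, Ifi47 0.28), NF-kB genes at 0.05 (Bcl3 0.49, Traf1 0.47), p53 targets at 0.09 (Plk2 1.02) and sex-linked genes at 0.58.

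In RUNX1(41-214) against control the means were -0.23 for quiescence, -0.16 for cell cycle (Cenpe -1.36), 0.01 for stromal (Col1a2 -0.76), -0.0047 for NF-kB (Birc3 0.71, Ccl3 -0.71), -0.04 for p53 target, 0.07 for Runx family (Ets1 -1.11, Tal1 0.31), 0.38 for reported Runx1 target, -0.05 for ribosome biogenesis (Gnl3 -0.28, Polr1a -0.39) and 0.45 for sex-linked genes. In RUNX1(41-214) against Runx1KO they were -0.29 for quiescence, -0.11 for cell cycle (Tyms 0.45), 0.11 for niche adhesion, 0.18 for erythroid, -0.09 for T and NK cell (Cd8a 0.91), 0.26 for mast cell and -0.04 for stromal genes. In the same comparison they were 0.13 for interferon-stimulated (Rsad2 0.98, Bst2 1.42), -0.38 for immediate early, -0.06 for NF-kB (Ptgs2 0.81), -0.14 for p53 target, -0.13 for Runx family (Cbfa2t3 -0.37), 0.14 for reported Runx1 target, 0.10 for ribosome biogenesis (Ubtf 0.46, Nop58 -0.42) and -0.13 for sex-linked genes.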
